A study of Mus musculus with 9 samples.

How the data were processed

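The data are microarray measurements of colon RNA from female BALB/c mice in 3 groups of 3 arrays each. Per the labels, Mock mice were untreated. Sham mice received the carcinogen azoxymethane (AOM) at 12.5 mg/kg on day 1. From day 8 they drank 2.5% dextran sodium sulfate (DSS), which injures the gut lining, for 5 days, then plain water for 16 days, with 3 additional cycles. Vanillin mice had the same AOM/DSS course and 100 mg/kg oral vanillin for 91 days. Other vanillin amounts that the series design mentions are not analysed here. The labels do not say whether the 3 arrays of a group come from separate mice, so the p-values measure only the spread between these arrays, which may be technical.

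The deposited values are the intensity of each probe, on a linear scale. Per the labels, RNA was amplified and labelled with Cy5, and per the submitters' processing notes limma was used, with neither its role nor its version given. The values themselves show background subtraction (3 to 14 probes per array lie below 0) and quantile normalization by the authors across the 9 arrays, since the sorted log2 values of any array differ by at most 0.109. The scanner, the background method, the summary of spots and any probe filter are not given in the sources used here. No centring or scaling by gene was seen. The median intensity was 319.6, 319.8 and 319.6 in Mock 1, 2 and 3, and 320.1 in each of Sham 1, 2 and 3. In Vanillin 1, 2 and 3 it was 320.1, 319.6 and 320.1. The highest value per array was near 65509, so the brightest probes (30 to 42 per array) sit at the top of the range, and their changes may be underestimated. About 20.0% of probes per array were below an intensity of 50.

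Every array had a value for all 26423 probes, and none was left out. The platform's probe table names 1 gene symbol for 20377 probes, several for 0 and none for 6046. The named probes cover 17742 genes, 2278 of them with more than 1 probe. Old symbols were replaced through a table of synonyms where only 1 gene was possible (2125 probes). Unnamed probes were tested and counted but are not described.

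Values were set to 0 where negative, and log2(value + 16) was taken. The arrays' quartiles differed by at most 0.0128 on that scale, under the 0.2 that would have called for another normalization, so the values were used as deposited. A linear model with 3 group means was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, two-sided moderated test), with 6 residual degrees of freedom and 2.69 prior ones. The comparisons are Sham minus Mock, Vanillin minus Sham and Vanillin minus Mock. The Benjamini-Hochberg adjustment ran over the 26423 probes within each comparison, and a probe was called at an adjusted p under 0.05, with no minimum change. Changes are given on the log2 scale with their standard error (SE). With 3 arrays per group, their number limits the precision. The median residual SD was 0.0895. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

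Before the data were examined, 41 gene lists were fixed from the series title (proteasome, NF-κB, MAPK), from AOM/DSS biology, from cell types a colon sample could hold and from control functions. Of these, 39 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, with 1 probe per gene (the brightest on average over all arrays) and adjustment over the 39 lists. The same test with a correlation estimated per list, and limma's fry, ran beside it. The lists of MHC class II genes (3 of 10 measured) and of erythroid genes (2 of 10 measured) were not tested. Additional lists for hair follicle, sebaceous gland, skeletal muscle, mammary gland, melanocyte and mesothelium were written after the values had been seen.

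The rule for the genes named in the text has 3 parts. In each comparison it takes the 12 largest increases and the 12 largest decreases among called probes with 1 informative gene symbol and no overlap between the arrays of the 2 groups. It adds up to 4 members of each described list with the smallest p. It also takes, whatever their values, genes of the title's pathways and of AOM/DSS colon biology (among them Psmb8, Psmb9, Psma1, Psmd14, Nfkb1, Rela, Nfkbia, Il1b, Il6, Tnf, Ptgs2, Cxcl1, Mapk14, Fos, Axin2, Mki67, Muc2, Slc26a3, Trpv1 and Trpa1). A gene with several probes is given by its brightest one. Genes outside the rule are said to be chosen after their values were seen.

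Sham minus Mock and Vanillin minus Sham share the Sham arrays with opposite sign, which by itself makes their changes run against each other. The covariance of the changes was therefore set beside 100 simulated draws without group effects, and beside a calculation with the Sham arrays split so that no array entered both. Simulated data had the number of arrays and the residual spread of the real ones, with only 50 probes per shift changed in Vanillin minus Sham. The model recovered 3 of 50 shifted by 0.25, 42 of 50 by 0.5, 43 of 50 by 1 and 49 of 50 by 2. There were 3 false calls. In the real comparison 47.9% of probes were called, which loosens the adjusted threshold, so these counts do not give its sensitivity. A list shifted by -0.5 was found, and 0 other lists were called. The simulated genes were uncorrelated, so this cannot show false list calls from correlated genes.

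Alternatives were another quantile normalization, median centring, leaving out the dimmest 30% of probes, a trended robust variance, fits of only the 6 arrays compared, the replicate number as a block, array weights, pseudocounts of 1 and 64, stricter thresholds, other list tests, the mean of all probes of a gene, and leaving out each array in turn.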

Results

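Values are log2 changes in probe intensity between groups of 3 arrays, given with SE, and "intensity" is the group's mean on the linear scale. Between arrays of the same group the correlation over all probes was 0.995 to 0.998. Between groups it was 0.926 to 0.929 for Mock with Sham, 0.969 to 0.973 for Mock with Vanillin and 0.964 to 0.967 for Sham with Vanillin.

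Sham minus Mock compares colons after the AOM/DSS course with untreated ones. The groups also differed in squamous epithelium and adipocyte markers (medians -5.2 and -4.21). Dilution by other tissue was not tested for this comparison, so its values do not separate AOM/DSS effects from a difference in tissue. Mmp7, a secreted protease of Paneth cells and intestinal tumours, rose by 8.24 (SE 0.068, adjusted p = 1.5e-12), from an intensity of 26.0 to 12800. The mucosal mast cell protease Mcpt2 rose by 7.99 (SE 0.057, adjusted p = 1.1e-12), and the antimicrobial lectins Reg3g and Reg3b rose by 7.02 and 6.65 (SE 0.086 and 0.051). Keratinocyte genes fell furthest: Krt1 fell by 9.72 (SE 0.053, adjusted p = 5.6e-13), from an intensity of 50500 to 43.9, and the adipokine gene Adipoq fell by 6.81 (SE 0.05, adjusted p = 1.2e-12). The transporter gene Slc26a3 of mature colonocytes fell by 2.98 (SE 0.089), while the mucin gene Muc2 rose by 1.35 (SE 0.053).

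The other genes among the 12 largest increases were the protease Mmp10 (7.44), the pancreatic lipase relative Pnliprp1 (6.67), the Wnt target Sp5 (5.96), the neutrophil gene Retnlg (5.80), Erich3 (5.77), the chemokine Cxcl2 (5.73), Otop1 (5.52) and Ceacam12 (5.18). Ceacam12 has other probes that rose by only 0.58 to 0.71. The largest decrease was that of Krtdap (-10.66, SE 0.54), whose Sham arrays had an SD of 1.38. The remaining decreases were those of Klk10 (-8.93), Cst6 (-8.87), Sprr1b (-8.79), Klk7 (-8.74), Sprr4 (-8.70), Defb6 (-8.67), Dsg1a (-8.66), Krt25 (-8.66), Fam25c (-8.66) and Hrnr (-8.58), most of them genes of skin or its appendages. A second probe of Cst6 gave 0.12. The sizes and order of changes that reach dim probes depend on the pseudocount: with 1 and 64 in place of 16, Krtdap had -12.42 and -9.34, Klk10 -9.87 and -7.61, Cst6 -9.09 and -8.33, and Mmp7 8.88 and 7.15. Fam25c was near the top of the intensity range in Mock (65500).

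Inflammatory and immune genes rose as groups. Of 23 measured NF-κB inflammatory targets, 21 rose and 2 were not called (median 1.89, adjusted p = 7.62e-09), among them Ccl3 (4.92), Ccl2 (2.67) and Ptgs2 (3.19, SE 0.061). Il1b rose by 3.87 (SE 0.074), Il6 by 3.19 (SE 0.063), Cxcl1 by 4.52 (SE 0.092) and Tnf by 0.72 (SE 0.044). The title of the series names this pathway, so the count of 21 is not independent evidence. Of 24 interferon-stimulated genes, 20 rose, 2 fell and 2 were not called (median 1.23, adjusted p = 7.7e-06), with Zbp1 at 3.21, Cxcl9 at 2.89 (1.25 on its second probe) and Usp18 at 2.45. The 2 that fell, named after their values were seen, were Mx1 (-0.62) and Irf1 (-0.64). Of 10 Paneth-type and antimicrobial genes, 8 rose and 2 were not called (median 2.18, adjusted p = 9.82e-05). Among them Pla2g2a reached the top of the range in Sham (65500), so its change of 5.18 may be too small. Of 14 matrix metalloproteinases and inhibitors, 12 rose, 1 fell and 1 was not called (median 1.75, adjusted p = 0.000183), among them Mmp13 (4.17) and the inhibitor Timp1 (2.87), which acts against these proteases.

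Neutrophil markers rose in 13 of 17 and fell in 4 (median 2.0, adjusted p = 0.0176), with Clec4d at 3.82 and Mmp8 at 4.24. The 4 that fell, named after their values were seen, were Ltf (-2.66), Il1r2 (-2.08), S100a8 (-1.19) and Mpo (-0.29). This call was lost at an adjusted p = 0.0888 with an estimated correlation. Mast cell and eosinophil markers rose in 11 of 14, fell in 2 and were not called in 1 (median 0.94, adjusted p = 0.0135), with Tpsab1 at 3.30 and Hdc at 3.55. That call was lost at an adjusted p = 0.172 with an estimated correlation. Of 15 B and plasma cell markers, 10 rose, 2 fell and 3 were not called (median 0.65, adjusted p = 0.0477), with Jchain at 3.16 and Mzb1 at 3.39, and the adjusted p = 0.195 with an estimated correlation. Their adjusted p was 0.0547 without Sham replicate 1, 0.06 without Sham replicate 2, 0.0561 without Vanillin replicate 1 and 0.052 without Vanillin replicate 3. It was 0.0814 without the dimmest 30% of probes, 0.0521 with only the 6 arrays compared, 0.0609 with array weights and 0.0606 with a pseudocount of 1. Macrophage markers (median 0.91, adjusted p = 0.069) and T and NK cell markers (median 0.27, adjusted p = 0.488) were not called as lists, although Spp1 rose by 3.23 and Gzmb by 4.17.

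Wnt and proliferation genes rose. Of 21 Wnt/β-catenin targets, 19 rose and 2 were not called (median 1.87, adjusted p = 2.6e-07), with Wif1 at 5.10, Nkd1 at 3.96 (2.19 on its second probe) and Axin2 at 2.29 (SE 0.045). Of 28 cell cycle genes, 27 rose and 1 was not called (median 1.25, adjusted p = 7.62e-09), with Top2a at 1.94, Ccna2 at 1.82 and Aurka at 1.75. Mki67 rose by 0.64 (SE 0.057) on its brightest probe and by 1.44 on the other. Colonocyte markers moved both ways, with 11 higher, 5 lower and 3 not called of 19 (median 0.22, adjusted p = 0.565). Cdx2 rose by 3.13 there while Slc26a3 fell. Of 13 goblet cell markers, 6 rose, 1 fell and 6 were not called (median 0.09, adjusted p = 0.423), and the goblet cell regulator Spdef was the member that fell (-0.87).

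Squamous epithelium, adipocyte and muscle genes fell. All 15 measured squamous epithelium markers fell (median -5.20, adjusted p = 2.39e-13), with Ivl at -7.58, Trp63 at -6.49 (-5.79 to -2.63 on its other probes) and Krt4 at -6.19. Of 12 adipocyte markers, 11 fell and 1 rose (median -4.21, adjusted p = 1.44e-08), with Cfd at -7.06, Cidea at -5.59 and Fabp4 at -3.90. The riser, named after its value was seen, was Lpl (0.17). Of 9 smooth muscle markers, 8 fell and 1 rose (median -1.88, adjusted p = 0.000102), with Des at -2.61 and Smtn at -2.28. The riser, also named afterwards, was Actn1 (0.47). In the lists written after the values had been seen, 17 of 19 hair follicle genes fell (median -4.43), 11 of 14 sebaceous gland genes fell (median -2.36) and all 12 skeletal muscle genes fell (median -5.41). Of 10 mammary gland genes 7 fell (median -2.10), and of 6 melanocyte genes 4 fell (median -0.84). Of 12 mesothelium genes, from a list written in the same way, 7 rose and 4 fell (median 1.02), and endothelial markers (4 higher, 5 lower and 6 not called of 15) and enteric neuron and glia markers (4 higher, 5 lower and 3 not called of 12) moved both ways.

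Of 14 xenobiotic metabolism genes, 10 fell and 4 rose (median -0.88, adjusted p = 0.00261), with Aldh3a1 at -3.57 and Aldh1a1 at -1.86, and the adjusted p = 0.153 with an estimated correlation. Of 17 glycolysis and hypoxia genes, 11 fell, 1 rose and 5 were not called (median -0.30, adjusted p = 0.00212), with Bnip3 at -1.65 and Slc2a1 at -1.24, and the adjusted p = 0.0515 with an estimated correlation. The riser was Hk2 (0.83). Fatty acid oxidation genes were not called (median -0.09, adjusted p = 0.0859), and of 24 oxidative phosphorylation genes 11 rose, 2 fell and 11 were not called (median 0.14, adjusted p = 0.302).

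None of the proteasome lists was called in this comparison. Of 12 genes of the 20S core, 10 rose, 1 fell and 1 was not called (median 0.35), with Psma5 at 0.82, Psma4 at 0.45 and Psma1 at 0.54 (SE 0.063), and the list was not called (adjusted p = 0.069). Psma5 was dim, with an intensity of 18.7 in Mock and 45.6 in Sham, so its size depends on the pseudocount. Of 21 genes of the 19S cap, 9 rose, 3 fell and 9 were not called (median 0.10, adjusted p = 0.391), with Psmd14 at 0.52 (SE 0.055). Of 7 immunoproteasome and PA28 genes, 5 rose and 2 fell (median 0.65, adjusted p = 0.26), with Psmb8 at 1.59 (SE 0.12), Psmb9 at 1.25 (SE 0.073) and Psmb10 at 1.04. Of 16 NF-κB subunits and feedback genes, 11 rose, 2 fell and 3 were not called (median 0.53, adjusted p = 0.13). Bcl3 rose by 1.59, as did the inhibitors Nfkbie (1.18) and Tnfaip3 (0.93), which restrain the pathway, but Nfkb1 fell by 3.05 (SE 0.05, adjusted p = 7.2e-11). Of 24 MAP kinases, 3 rose, 10 fell and 11 were not called (median -0.08, adjusted p = 0.069), with Mapk12 at -2.13 and Mapk14 at -0.26 (SE 0.053). Of 19 MAPK-responsive early genes, 6 rose, 8 fell and 5 were not called (median 0.00, mean -0.05, test downward, adjusted p = 0.491), with Egr2 at -3.93, Jun at 1.35 and Fos at -0.35 (SE 0.053). Since the title names these pathways, the counts are not independent evidence. Among ion channel genes, Trpa1 rose by 1.31 (SE 0.12) and Trpv1 fell by 0.79 (SE 0.083), at intensities of 135 and 21.4 in Sham.

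Rela rose by 0.25 (SE 0.081, adjusted p = 0.026) and Nfkbia fell by 0.23 (SE 0.077, adjusted p = 0.026), both near the threshold. The adjusted p of Rela was 0.0643 without Mock replicate 2, 0.0675 without Mock replicate 3, 0.0666 without Sham replicate 1 and 0.0896 without Sham replicate 3. That of Nfkbia was 0.0876 without Mock replicate 2, 0.0889 without Sham replicate 1, 0.0618 without Sham replicate 2 and 0.0531 with only the 6 arrays compared.

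In Sham minus Mock, 15787 of 26423 probes (59.7%) were called, 9648 higher and 6139 lower, and 1559 and 2000 of them changed by at least 1. The 2 groups' arrays did not overlap for 67.1% of probes, where chance gives 10%. Of the 39 lists, 14 were called, 9 up and 5 down, and 9 of the 14 held with an estimated correlation. The uncalled lists had adjusted p from 0.069 to 0.799. Adjusted over the list alone, 20 Wnt/β-catenin targets, 21 interferon-stimulated genes and 10 oxidative phosphorylation genes rose, and the other counts given above were the same. Median and mean of a list differed in sign from each other or from its test in 4 uncalled lists: MAPK-responsive early genes, endothelial markers (median 0.02, mean 0.04, test downward), pancreatic acinar markers (median 0.20, mean -0.06, test downward) and Nrf2 targets (median 0.09, mean -0.11, test downward).

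**Figure D1:**
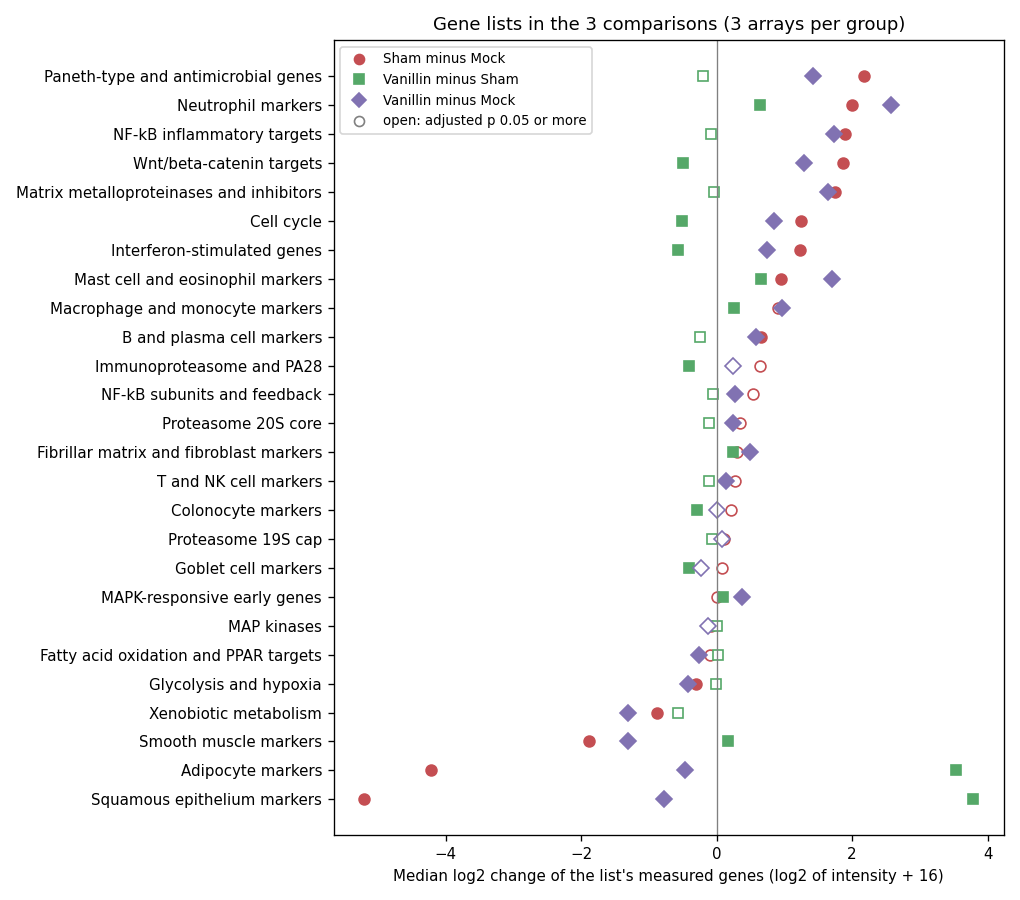
Median log2 change of each gene list (horizontal axis, log2 of intensity + 16) in the 3 comparisons, for lists called in at least 1 of them and for the 19S cap and MAP kinase lists. Filled symbols have an adjusted p under 0.05, and the squamous epithelium list moved from -5.20 in Sham minus Mock to 3.79 in Vanillin minus Sham.

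Vanillin minus Sham compares mice on the AOM/DSS course with and without vanillin. Interferon-stimulated, cell cycle and Wnt genes were lower with vanillin: Cxcl9 fell by 1.70 (SE 0.058, adjusted p = 3.0e-08, and -1.23 on its second probe), Top2a by 0.59 (SE 0.046, adjusted p = 1.1e-05) and Axin2 by 0.50 (SE 0.045, adjusted p = 2.8e-05). The Wnt list had an adjusted p = 0.07 with an estimated correlation. Neutrophil genes were higher, with Il1r2 at 1.78 (SE 0.053, adjusted p = 1.1e-08), which had fallen by 2.08 in Sham minus Mock. The cytokine gene Il1b, already higher in Sham than in Mock, rose by a further 1.53 (SE 0.074, adjusted p = 4e-07). The immunoproteasome gene Psmb8 fell by 0.84 (SE 0.12, adjusted p = 0.00036). The largest increases were in genes of skin and fat, such as Krt1 (8.69, SE 0.053) and Adipoq (6.59, SE 0.05).

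Of 24 interferon-stimulated genes, 22 fell, 1 rose and 1 was not called (median -0.58, adjusted p = 6.44e-06), with Zbp1 at -1.21, Ifit2 at -1.01 and Gbp3 at -0.77. The riser, named after its value was seen, was Irf1 (0.69). This call held at an adjusted p = 0.0323 with an estimated correlation. Of 28 cell cycle genes, 23 fell and 5 were not called (median -0.50, adjusted p = 3.11e-05), with Bub1b at -0.79, Kif11 at -0.63 and Aurka at -0.61, and Mki67 fell by 0.58 (SE 0.057). Of 21 Wnt/β-catenin targets, 15 fell, 2 rose and 4 were not called (median -0.50, adjusted p = 0.00813), with Mmp7 at -1.07, Sox4 at -0.86 and Dkk2 at -0.81. The adjusted p = 0.07 with an estimated correlation. The 2 risers, named after their values were seen, were Apcdd1 (0.91) and Tnfrsf19 (0.56).

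Of 19 colonocyte markers, 15 fell, 1 rose and 3 were not called (median -0.29, adjusted p = 0.0244, and adjusted p = 0.1 with an estimated correlation). Cdx2 fell by 0.61, Guca2a by 0.59 and Slc26a3 by 0.49 (SE 0.089), and Emp1 was the riser (0.67). Of 13 goblet cell markers, 8 fell and 5 were not called (median -0.41, adjusted p = 0.0174, and adjusted p = 0.182 with an estimated correlation), with Atoh1 at -1.27, Zg16 at -0.88, Tff3 at -0.61 and Muc2 at -0.50 (SE 0.053). Enteroendocrine and tuft cell markers moved both ways (6 higher, 7 lower and 3 not called of 16, adjusted p = 0.503). B and plasma cell markers were not called (median -0.24, adjusted p = 0.456), although Derl3 fell by 1.03.

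Myeloid and mast cell genes were higher. Of 17 neutrophil markers, 14 rose and 3 were not called (median 0.65, adjusted p = 9.28e-08), with Trem1 at 1.55, Clec4d at 1.17 and Retnlg at 1.00. Of 17 macrophage and monocyte markers, 10 rose, 1 fell and 6 were not called (median 0.25, adjusted p = 0.00138), with Cd163 at 2.29 and Arg1 at 0.72, and Mertk was the member that fell (-0.41). Squamous epithelium (median 3.79), adipocyte (median 3.53) and hair follicle genes (median 3.57) rose in the same comparison. Cd163 shared their order, with intensities of 848, 107 and 584 in Mock, Sham and Vanillin. So did the neutrophil marker Il1r2, which was lower in Sham than in Mock and higher again with vanillin. Trem1, Clec4d and Retnlg, in contrast, had already risen in Sham minus Mock. Of 14 mast cell and eosinophil markers, 10 rose, 2 fell and 2 were not called (median 0.65, adjusted p = 0.000127), with Cpa3 at 0.94 and Hdc at 0.77, and the adjusted p = 0.07 with an estimated correlation. Of 19 fibrillar matrix and fibroblast markers, 10 rose, 2 fell and 7 were not called (median 0.24, adjusted p = 0.00137), with Lum at 1.65 and Postn at 0.91. The 2 that fell, named after their values were seen, were Tnc (-0.40) and Fn1 (-0.28). Of 9 smooth muscle markers, 5 rose and 4 were not called (median 0.17, adjusted p = 0.0128, and adjusted p = 0.087 with an estimated correlation), with Des at 0.76. As a list, the smooth muscle markers also shared the order of the squamous epithelium and adipocyte genes. They were lowest in Sham and highest in Mock (medians -1.88 in Sham minus Mock and -1.31 in Vanillin minus Mock).

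The NF-κB inflammatory targets split, with 8 higher, 9 lower and 6 not called of 23 (median -0.07, mean 0.12, test upward, adjusted p = 0.383). Cxcl2 rose by 1.20 (SE 0.049), Il1a by 1.27 and Ptgs2 by 0.90 (SE 0.061), while Ccl20 fell by 1.01. Il6 (0.04, SE 0.063), Tnf (0.06, SE 0.044) and Cxcl1 (0.19, SE 0.092, adjusted p = 0.12) were not called, but Cxcl1 had an adjusted p = 0.0451 without Vanillin replicate 1. Of 16 NF-κB subunits and feedback genes, 4 rose, 5 fell and 7 were not called (median -0.05, mean 0.04, test upward, adjusted p = 0.737). Nfkb1 rose by 2.65 (SE 0.05, adjusted p = 4.1e-10), back to an intensity of 4690 from 736, against 6230 in Mock. Squamous epithelium and adipocyte markers had the same order of groups (Vanillin minus Sham medians 3.79 and 3.53). Relb fell by 0.48, Nfkb2 by 0.45 and Bcl3 by 0.40. Rela was not called (-0.18, SE 0.081, adjusted p = 0.099), but its adjusted p was 0.0171 without Vanillin replicate 1 and 0.0262 with array weights. The rise of Nfkbia by 0.26 (SE 0.077, adjusted p = 0.021) was not called without Sham replicate 1 (0.0731), Sham replicate 2 (0.0533), Vanillin replicate 2 (0.0552) or Vanillin replicate 3 (0.0561). Since the title names the pathway, these counts are not independent evidence.

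Of 7 immunoproteasome and PA28 genes, 6 fell and 1 was not called (median -0.41, adjusted p = 0.0287, and adjusted p = 0.37 with an estimated correlation), with Psmb10 at -0.65, Psmb9 at -0.53 (SE 0.073) and Psme3 at -0.35. The 32 colonocyte and goblet cell genes had a median of -0.37 in the same comparison, so this list fell about as far. Dilution by other tissue was not tested for it. Of 12 genes of the 20S core, 4 fell and 8 were not called (median -0.12, adjusted p = 0.51), and of 21 genes of the 19S cap, 6 fell and 15 were not called (median -0.07, adjusted p = 0.737). Psma5 fell by 0.53, at an intensity of 26.4 against 45.6 in Sham, and Psma4 by 0.20. Psma1 fell by 0.24 (SE 0.063, adjusted p = 0.014), Psmc4 by 0.25 and Psmd2 by 0.31, and Psmd14 was not called (-0.06, SE 0.055, adjusted p = 0.41). Of 24 MAP kinases, 6 rose, 6 fell and 12 were not called (median 0.00, adjusted p = 0.473), with Mapk12 at 0.80, Map3k5 at -0.74 and Mapk14 not called (0.05, SE 0.053, adjusted p = 0.5). Mapk12 had the order of groups of the squamous epithelium and adipocyte markers, lowest in Sham and highest in Mock. Of 19 MAPK-responsive early genes, 8 rose, 4 fell and 7 were not called (median 0.09, adjusted p = 0.0165, and adjusted p = 0.287 with an estimated correlation). Egr2 rose by 3.57, in the same order as those tissue markers (intensities of 3660, 226 and 2850 in Mock, Sham and Vanillin), Egr1 by 0.94 and Fos by 0.51 (SE 0.053), and Dusp1, whose product switches MAP kinases off, rose by 1.00. These lists come from the title, so the counts are not independent evidence. Trpa1 was not called (0.17, SE 0.12, adjusted p = 0.28), but its adjusted p was 0.0465 with only the 6 arrays compared.

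Some proteasome and channel calls depend on the arrays or settings used. Psmb2 (-0.14, adjusted p = 0.034) was not called without Mock replicate 2 (0.0501), Mock replicate 3 (0.0584), Sham replicate 1 (0.095), Sham replicate 3 (0.0798), Vanillin replicate 2 (0.106) or Vanillin replicate 3 (0.0748), nor with only the 6 arrays compared (0.0756). Psmd4 (-0.16, adjusted p = 0.02) was not called without Sham replicate 3 (0.0598) or Vanillin replicate 2 (0.0691). Psmd9 (-0.30, adjusted p = 0.035) was not called without Sham replicate 1 (0.0719), Sham replicate 2 (0.0703), Sham replicate 3 (0.0906), Vanillin replicate 2 (0.0911) or Vanillin replicate 3 (0.0979). Trpv1 (-0.26, SE 0.083, adjusted p = 0.027) was not called without Sham replicate 1 (0.0785), Vanillin replicate 2 (0.0828) or Vanillin replicate 3 (0.078), nor with a pseudocount of 64 (-0.11, adjusted p = 0.0749), and its intensity was only 15.1 with vanillin.

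Among the 12 largest increases, after Krtdap (10.36, SE 0.54), came Hrnr (9.02), Defb6 (8.97), Cst6 (8.87), Klk7 (8.79), Krt1, Fam25c (8.51), Sprr4 (8.29), Krt77 (8.11), Dsg1a (8.08), Sdr16c6 (7.99) and Lce1a2 (7.68). Krtdap again had an SD of 1.38 in Sham, and the second probe of Cst6 gave -0.04. Here too the sizes depend on the pseudocount, with Krtdap at 12.12 and 9.04 for pseudocounts of 1 and 64. Of 15 squamous epithelium markers, 14 rose and 1 was not called (median 3.79, adjusted p = 9.77e-19), with Ivl at 6.86, Trp63 at 5.72 (1.35 to 4.88 on its other probes) and Lor at 5.30, the last near the top of the range (65100). The member not called, Krt14 (0.99), was named after its value was seen. Of 12 adipocyte markers, 11 rose and 1 fell (median 3.53, adjusted p = 1.45e-11), with Cfd at 6.97 and Fabp4 at 3.98, and Lpl, named in the same way, fell by 0.49. In the lists written after the values had been seen, 17 of 19 hair follicle genes rose (median 3.57), 12 of 14 sebaceous gland genes rose (median 2.23) and 10 of 12 skeletal muscle genes rose (median 3.26). Of the 10 mammary gland genes 3 rose and 7 were not called (median 0.02), and of 6 melanocyte genes 3 rose (median 0.45).

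The decreases were smaller than the increases. The cell cycle inhibitor gene Cdkn2a fell by 2.16 (SE 0.075) on both probes (-2.38 on the other), Timp2 by 1.97, Pigt by 1.95, Apob by 1.83 and the interferon-γ induced gene Ubd by 1.72. Upk3b fell by 2.0 (SE 0.049), Gata5 by 1.77 and Lrrn4 by 1.76. These 3 belong to a list of 12 mesothelium genes, written after the values had been seen, of which 8 fell, 2 rose and 2 were not called (median -0.78, and -0.33 for the 9 members not among the largest changes). Ifit3b had the largest decrease (-3.75, SE 1, adjusted p = 0.015) with an SD of 2.62 between the vanillin arrays, and without Vanillin replicate 2 it was -2.98 (adjusted p = 0.0522). Rps29 (-1.99, SD 1.07 with vanillin) and Coa7 (-1.75, SD 1.18 in Sham) were also uneven, at intensities of 113 and 61.9 in Sham.

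In Vanillin minus Sham, 12659 probes (47.9%) were called, 4141 higher and 8518 lower, and 1005 and 177 of them changed by at least 1. The 2 groups' arrays did not overlap for 56.3% of probes, where chance gives 10%. Of the 39 lists, 14 were called, 8 up and 6 down, and 7 held with an estimated correlation. The uncalled lists had adjusted p from 0.112 to 0.954. Adjusted over the list alone, 24 cell cycle genes, 17 Wnt/β-catenin targets, 16 colonocyte markers and 2 genes of the 19S cap fell, 11 fibroblast and 11 macrophage markers and 5 NF-κB subunits and feedback genes rose, and 1 neutrophil marker fell. Of the enteroendocrine and tuft cell markers, 7 rose. The other counts given above were the same. Besides the 2 NF-κB lists, median and mean differed in sign in the T and NK cell markers (median -0.12, mean 0.02, adjusted p = 0.538), the glycolysis list (median -0.00, mean 0.00, adjusted p = 0.546) and the heat shock proteins (median -0.29, mean 0.19, adjusted p = 0.739), each with an upward test.

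**Figure D2:**
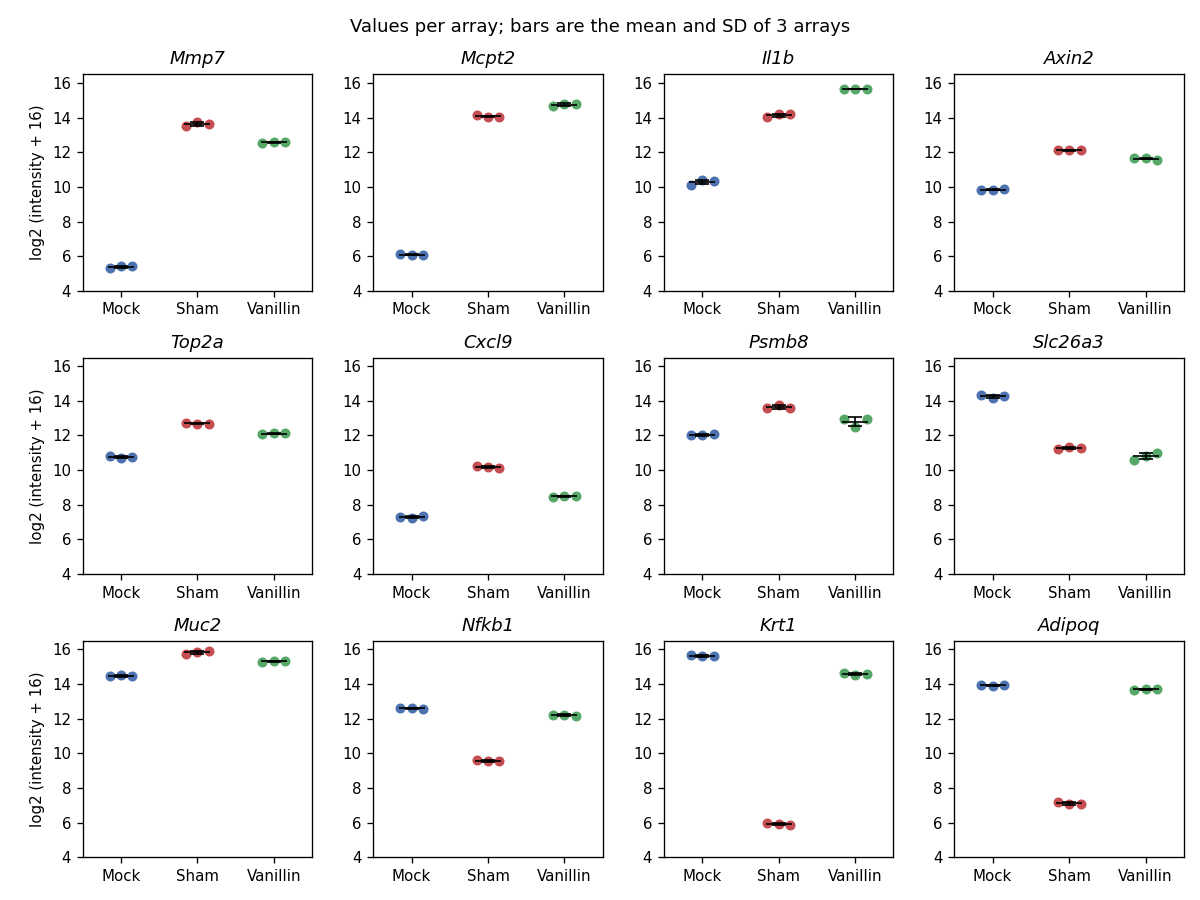
Values per array (log2 of intensity + 16) of 12 genes in the 3 groups, with the mean and SD of 3 arrays. Il1b, Mcpt2 and Mmp7 stayed far above Mock with vanillin, while Krt1, Adipoq and Nfkb1 were lowest in Sham.

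Vanillin minus Mock compares vanillin-treated AOM/DSS colons with untreated ones. Mcpt2 was 8.65 higher (SE 0.057, adjusted p = 4.8e-12) and Reg3b 7.79 higher (SE 0.051, adjusted p = 4.8e-12). Il1b was 5.39 higher (SE 0.074), with an intensity of 52000 against 1230, and Cxcl2 was 6.93 higher (SE 0.049). The Wnt target Axin2 was 1.79 higher (SE 0.045) and Slc26a3 was lower (-3.47, SE 0.089). The gel-forming mucin gene Muc5b was lower by far (-6.80, SE 0.1, adjusted p = 2.2e-10), while the mucin gene Muc2 was higher. Squamous epithelium, skeletal muscle and mammary gland genes were also lower (medians -0.78, -1.83 and -1.50), though not sebaceous gland genes (median 0.00). These values therefore do not separate treatment effects from a difference in tissue.

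The other large increases were Mmp10 (7.49), Mmp7 (7.18), Retnlg (6.79), Reg3g (6.73), Pnliprp1 (6.62), Acod1 (6.17), Ccl3 (5.65) and Ccl4 (5.45). A second probe of Acod1 gave 1.5. The other large decreases were Krt76 (-6.46), Cldn22 (-5.89), the milk protein gene Csn1s2a (-5.72), Tmem213 (-5.56), Csn1s1 (-5.49), the stem cell gene Olfm4 (-5.14), Gp2 (-5.06), the fast muscle gene Pvalb (-5.04), Krt16 (-5.04), Padi1 (-4.56) and Sprr3 (-4.44).

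Of 23 NF-κB inflammatory targets, 20 were higher, 1 lower and 2 not called (median 1.74, adjusted p = 1.22e-11), a count that the title makes not independent evidence. Ptgs2 was 4.08 higher (SE 0.061), Cxcl1 4.71 (SE 0.092), Il6 3.24 (SE 0.063) and Tnf 0.78 (SE 0.044). The member that was lower, named after its value was seen, was Csf3 (-0.48). Of 21 Wnt/β-catenin targets, 19 were higher and 2 not called (median 1.29, adjusted p = 1.8e-10), with Sp5 at 5.19 and Wif1 at 4.95. Of 28 cell cycle genes, 24 were higher and 4 not called (median 0.85, adjusted p = 3.89e-10), with Ccna2 at 1.48. Mki67 was not called on its brightest probe (0.07, SE 0.057, adjusted p = 0.35), but the other probe gave 0.94 and the mean of both gave 0.51 (adjusted p = 1.14e-05), and with array weights the brightest probe had 0.13 (adjusted p = 0.0285). Of 24 interferon-stimulated genes, 18 were higher, 1 lower and 5 not called (median 0.75, adjusted p = 5.25e-06), with Usp18 at 2.08, and Mx1, named after its value was seen, was the lower one (-1.39). Of 10 Paneth-type and antimicrobial genes, 8 were higher and 2 not called (median 1.43, adjusted p = 4.26e-06). Of 14 matrix metalloproteinases and inhibitors, 9 were higher, 1 lower and 4 not called (median 1.64, adjusted p = 9.02e-06), with Mmp13 at 4.31.

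Neutrophil markers were higher in 13 of 17, lower in 3 and not called in 1 (median 2.57, adjusted p = 6.94e-06), with Trem1 at 5.20 and Clec4d at 4.99. Macrophage and monocyte markers were higher in 14 of 17 and lower in 3 (median 0.97, adjusted p = 5.42e-05), with Spp1 at 3.13 and Cd14 at 2.62. Mast cell and eosinophil markers were higher in 9 of 14, lower in 2 and not called in 3 (median 1.70, adjusted p = 6.2e-05), with Hdc at 4.32. Fibrillar matrix and fibroblast markers were higher in 14 of 19, lower in 2 and not called in 3 (median 0.49, adjusted p = 0.00119), with Loxl2 at 1.80 (1.15 on its second probe). B and plasma cell markers were higher in 9 of 15, lower in 2 and not called in 4 (median 0.58, adjusted p = 0.00202, and adjusted p = 0.0782 with an estimated correlation), with Jchain at 2.62. T and NK cell markers were higher in 7 of 19, lower in 1 and not called in 11 (median 0.14, adjusted p = 0.0338, and adjusted p = 0.091 with an estimated correlation), with Gzmb at 3.37. This last call was also lost without the dimmest 30% of probes (0.0556) and with array weights (0.058).

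Of 12 genes of the 20S core, 9 were higher, 1 lower and 2 not called (median 0.24, adjusted p = 0.0259, and adjusted p = 0.0865 with an estimated correlation), with Psma2 at 0.37 and Psma1 at 0.30 (SE 0.063). It was also lost without the dimmest 30% of probes (adjusted p = 0.0665). Of 21 genes of the 19S cap, 5 were higher, 3 lower and 13 not called (median 0.08, adjusted p = 0.301), with Psmd14 at 0.46 (SE 0.055). Of 7 immunoproteasome and PA28 genes, 4 were higher, 2 lower and 1 not called (median 0.24, adjusted p = 0.41), with Psmb8 at 0.75 (SE 0.12), Psmb9 at 0.73 (SE 0.073) and Psme2 at -0.68. Of 16 NF-κB subunits and feedback genes, 9 were higher, 2 lower and 5 not called (median 0.27, adjusted p = 0.0223, and adjusted p = 0.091 with an estimated correlation), with Bcl3 at 1.19 and Nfkb1 at -0.41 (SE 0.05). Rela (0.07, SE 0.081, adjusted p = 0.53) and Nfkbia (0.03, SE 0.077, adjusted p = 0.81) were not called, and their values changed sign when 1 array was left out: Rela was -0.01 without Vanillin replicate 1, and Nfkbia was -0.01 without Mock replicate 1 and -0.01 without Mock replicate 3. Of 24 MAP kinases, 2 were higher, 9 lower and 13 not called (median -0.13, adjusted p = 0.084), with Mapk12 at -1.33 and Mapk14 at -0.21 (SE 0.053). Of 19 MAPK-responsive early genes, 11 were higher, 4 lower and 4 not called (median 0.38, adjusted p = 0.0449, and adjusted p = 0.288 with an estimated correlation). That call was lost without Mock replicate 1 (median 0.23, adjusted p = 0.0818) and without Sham replicate 3 (0.0506), and also without the dimmest 30% of probes (0.0787) and with array weights (0.058). It included Dusp4 (1.49), Dusp6 (0.81) and Dusp1 (0.73), whose products switch MAP kinases off. These lists come from the title, so their counts are not independent evidence. Fos (0.15, SE 0.053, adjusted p = 0.039) was not called without Mock replicate 1 (0.0632), Mock replicate 2 (0.0677), Mock replicate 3 (0.131), Vanillin replicate 2 (0.102) or Vanillin replicate 3 (0.102).

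Of 15 squamous epithelium markers, 12 were lower and 3 not called (median -0.78, adjusted p = 5.25e-06), with Krt4 at -3.81 and Krt13 at -3.34, members that line moist surfaces. Of 9 smooth muscle markers, 8 were lower and 1 higher (median -1.31, adjusted p = 0.000177), with Cnn1 at -1.92 and Smtn at -1.90. Of 12 adipocyte markers, 9 were lower and 3 not called (median -0.46, adjusted p = 0.00119, and adjusted p = 0.0557 with an estimated correlation), with Plin4 at -1.07. In the lists written after the values had been seen, 12 of 12 skeletal muscle genes (median -1.83), 16 of 19 hair follicle genes (median -0.90) and 7 of 10 mammary gland genes (median -1.50) were lower. Sebaceous gland genes had 2 higher, 5 lower and 7 not called (median 0.00), and 3 of 6 melanocyte genes were lower (median -0.30). Of 14 xenobiotic metabolism genes, 10 were lower, 2 higher and 2 not called (median -1.31, adjusted p = 6.2e-05, and adjusted p = 0.054 with an estimated correlation), with Abcb1a at -2.39 and Sult1d1 at -2.02. Of 17 glycolysis and hypoxia genes, 13 were lower, 2 higher and 2 not called (median -0.42, adjusted p = 0.00119), with Pdk1 at -1.33. Of 19 fatty acid oxidation and PPAR targets, 11 were lower, 2 higher and 6 not called (median -0.25, adjusted p = 0.0233, and adjusted p = 0.0865 with an estimated correlation), with Ppara at -1.15 (-0.51 on its second probe). Goblet cell markers were not called (median -0.23, adjusted p = 0.17), with Muc2 at 0.85 (SE 0.053) and Spdef at -1.31. Colonocyte markers were not called either (median 0.01, mean -0.28, test upward, adjusted p = 0.957), with Cdx2 at 2.52, Car4 at -3.12 and Car1 at -2.12 (-2.02 to -0.27 on its other probes). Trpa1 was 1.49 higher (SE 0.12) and Trpv1 was lower (-1.05, SE 0.083).

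In Vanillin minus Mock, 13404 probes (50.7%) were called, 6473 higher and 6931 lower, and 972 and 1059 of them changed by at least 1. The 2 groups' arrays did not overlap for 60.4% of probes, where chance gives 10%. Of the 39 lists, 21 were called, 15 up and 6 down, and 13 held with an estimated correlation. The uncalled lists had adjusted p from 0.0778 to 0.957. Adjusted over the list alone, 11 metalloproteinases and inhibitors, 14 neutrophil markers and 9 Paneth-type genes were higher and 2 NF-κB inflammatory targets were lower, and the other counts given above were the same.

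Genes that differed between Sham and Mock tended to differ the other way between Vanillin and Sham, but by unequal parts. Markers of other tissues did so as well: the medians were -5.20 and then 3.79 for squamous epithelium, -4.21 and 3.53 for adipocytes, -4.43 and 3.57 for hair follicle and -5.41 and 3.26 for skeletal muscle. Krt1 had intensities of 50500, 43.9 and 24700 in Mock, Sham and Vanillin, and Adipoq had 15500, 122 and 13300. Psmb8 (1.59, then -0.84) moved part of the way, as did Cxcl9 on its brightest probe (2.89, then -1.70) but not on its second (1.25, then -1.23), Axin2 (2.29, then -0.50) less, and Il1b (3.87, then 1.53) moved further from Mock. Of the 9648 probes higher in Sham than in Mock, 5750 (59.6%) were called lower with vanillin, 403 were called higher, and 3644 (37.8%) were not called in Vanillin minus Mock. Calls made independently would give 3110 called lower. Of the 6139 probes lower in Sham, 3153 (51.4%) were called higher with vanillin, 640 were called lower, and 1370 (22.3%) were not called in Vanillin minus Mock, with 962 called higher if independent. A missing call in Vanillin minus Mock does not show equal levels.

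Of the 1005 probes at least 1 higher with vanillin than in Sham, 927 (92.2%) had been at least 1 lower in Sham than in Mock, against 76 if independent. Of the 177 at least 1 lower with vanillin, Cxcl9 among them, 117 (66.1%) had been at least 1 higher in Sham, against 10 if independent. The count of 177 was 107 with a pseudocount of 64 and 254 with array weights. The covariance of the 2 sets of changes over all probes was -0.55 (r = -0.79 across probes, which are not independent replicates). In simulation the shared Sham arrays alone gave a covariance of -0.01 on average, from -0.02 to -0.01, and an r of -0.5. The difference in covariance was -0.54, and with the Sham arrays split the covariance was -0.541 (r = -0.77). The opposite sign was found for 81.5% of the probes called in Sham minus Mock, for 80.0% with the Sham arrays split, and for 53.8% in simulation without a vanillin effect. In all, 8903 probes were called in opposite directions. That simulation gave 0.05, but with no vanillin effect almost no probe can be called in Vanillin minus Sham. Its count was thus fixed in advance and does not tell a move back from other changes. Neither the simulation nor the split removes a difference in tissue between the Sham arrays and the others.

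**Figure D3:**
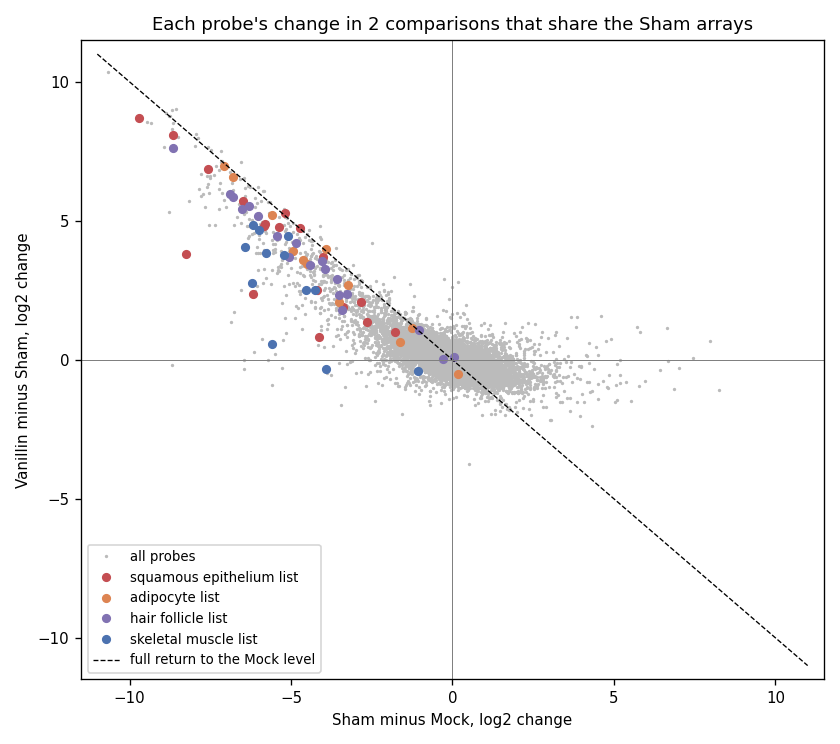
Log2 change of each probe in Sham minus Mock (horizontal) against Vanillin minus Sham (vertical), with 4 gene lists coloured and a dashed line where vanillin would restore the Mock level. Of the squamous epithelium genes 12 of 15 stayed lower than in Mock with vanillin, and the skeletal muscle and hair follicle lists were written after the values had been seen.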

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

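The 3 comparisons' counts of called probes stayed within 1.5 times of those reported under the normalization, filter, variance, array weight and pseudocount alternatives. They fell by the rule's own construction to 3559, 1182 and 2031 when a change of at least 1 was also required. Leaving out 1 array at a time gave 14265 to 16222 probes for Sham minus Mock, 10802 to 12752 for Vanillin minus Sham and 11679 to 13648 for Vanillin minus Mock. It gave 13 to 14, 14 to 14 and 20 to 21 called lists, a covariance of -0.559 to -0.547 and 7879 to 8826 probes called in opposite directions. Called lists numbered 9, 7 and 13 with an estimated correlation and 37, 35 and 37 with fry, which does not compare a list with other genes. The covariance was -0.738 without the dimmest 30% of probes, -0.655 with a pseudocount of 1, -0.426 with one of 64 and -0.541 with the Sham arrays split. Its spread between leave-one-out values was an SD of 0.00344. The pseudocount acts on dim probes, and the cause was not tested further. Only the 49 list calls of the 3 comparisons were followed through the settings: 993 results kept the direction and side of the threshold, 36 lost the call and 0 reversed. Uncalled lists were left out of that count. With the replicate number as a block, 15 lists were called in Sham minus Mock, against 14. The uncalled colonocyte markers in Vanillin minus Mock were upward by camera and downward by fry. For single genes, 9713 kept both, 60 lost a call, 17 gained one and 3 changed sign: in Vanillin minus Mock, Rela (-0.013 without Vanillin replicate 1) and Nfkbia (-0.011 without Mock replicate 1 and -0.01 without Mock replicate 3), all uncalled, for causes not tested. The same 2 values reached 0.132 without Vanillin replicate 3 (Rela) and 0.096 without Mock replicate 2 (Nfkbia), still uncalled, and the cause was not tested. Signal over background limits the dimmest genes, such as Trpv1.

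With the replicate number as a block, 15498, 12269 and 13021 probes were called in the 3 comparisons. Psmd9 in Vanillin minus Sham (adjusted p = 0.0556) and, in Vanillin minus Mock, the MAPK-responsive early genes (0.0501) and Fos (0.0673) lost their calls. The labels do not say that equal numbers pair arrays. After removing group means, arrays with the same number correlated at 0.13 to 0.20 for Vanillin with Sham, -0.12 to -0.016 for Sham with Mock and -0.29 to -0.10 for Vanillin with Mock, and 0 of 9 arrays correlated best with their own number in both other groups.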

Other observations

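The tests on hair follicle and skeletal muscle genes, on dilution and on other splits of the arrays were chosen only after the results they concern had been seen. Those on probes of equal brightness were not.

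Some mesothelium genes, from a list of 12 written after the values were seen, were high in Sham. Msln, a surface protein of mesothelium and of some carcinomas, rose by 4.38 in Sham minus Mock and stayed high with vanillin (4.05 above Mock). Upk1b (2.49), Gata5 (2.35), Lrrn4 (1.77), Upk3b (1.64) and Wt1 (1.46) also rose in Sham, and with vanillin they fell by 1.47, 1.77, 1.76, 2.0 and 1.53. Other members went the other way, with Rspo1 at -2.19 and then 1.12 and Bnc1 at -1.65 and then 0.63. Of the 12, 7 rose, 4 fell and 1 was not called in Sham minus Mock, where the list was not called (median 1.02, adjusted p = 0.218). The 9 members not among the largest changes had medians of 0.14 in Sham minus Mock and -0.33 in Vanillin minus Sham.

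Of 10 mammary gland genes, from a list written after the values were seen, 7 were lower in Sham than in Mock. In Mock, Sham and Vanillin, the milk protein gene Csn2 had intensities of 8420, 725 and 676, Csn1s1 had 5430, 30.8 and 105, Csn1s2a had 2350, 29.0 and 29.0, and the progesterone receptor gene Pgr had 6050, 191 and 569. The milk protein gene Wap fell by only 0.69 in Sham minus Mock (60.4, 31.3 and 31.4), and 3 were not called: Csn1s2b had 257, 265 and 258, Lalba 179, 173 and 176, and Csn3 only 3.77, 4.33 and 4.51. These genes were chosen after their values were seen. No explanation was tested for them, nor for the higher myeloid genes with vanillin. The first principal component held 74.9% of the variance and placed Mock at -80.2 to -79.2, Vanillin at -5.93 to -4.51 and Sham at 84.1 to 85.7, while the second (17.0%) set Vanillin apart. The squamous epithelium score had an SD of 0.012 between the Mock arrays, 0.0215 between the Sham arrays and 0.0821 between the Vanillin arrays.

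Most squamous epithelium, adipocyte, hair follicle and skeletal muscle genes were lower in Sham than in Mock and Vanillin, though not Actn3 (intensities of 1140, 60.1 and 43.8 in Mock, Sham and Vanillin) or Cacna1s (462, 213 and 156), both chosen after their values were seen. Probes outside the lists with the brightness of the squamous genes (738 probes) had a median Sham minus Mock change of 0.15. The squamous list had -5.20, so it fell much further than such probes. Quantile normalization favours medians near 0, so this comparison cannot decide whether normalization is part of the cause. If Mock and Vanillin arrays held tissue beside the colon, its other genes should follow. Hair follicle genes not among the largest changes (18 of 19) had a median of -4.23 in Sham minus Mock, and such skeletal muscle genes (11 of 12) -5.23. Both lists were written after the values had been seen, and nearly all members remain, so these medians are not an independent test. RNA from skin with its follicles and muscle, as from the end of the gut, is a candidate source. Krt71 had intensities of 36200, 382 and 16900 in Mock, Sham and Vanillin, and Acta1 had 35300, 1020 and 22900 (both chosen after their values were seen). No member of either list is in another list, which only describes how the lists were written. In Sham, 12 of 19 hair follicle genes had an intensity of 100 or more. An intensity of 100 lies below the Sham arrays' median of 320.1, so that cut alone does not show that these genes were expressed there. The labels say only colon, and no step that would remove such tissue is given. Mock mice were untreated per the labels, so AOM/DSS or vanillin cannot account for the high values in Mock. Whether either changed these tissues in the Sham or Vanillin mice stays open and untested.

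Interferon, cell cycle and Wnt genes were lower with vanillin than in Sham, the Wnt list with an adjusted p = 0.07 with an estimated correlation. Probes of equal mean brightness (3114 probes) had a median change of -0.11, against -0.53 for the 73 genes of the 3 lists, so the lists fell further than such probes. Quantile normalization had made the arrays' distributions equal, which favours medians near 0. That comparison therefore cannot decide whether normalization is part of the cause. Added RNA from other tissue could dilute all colon genes alike, so each list was set against colonocyte and goblet cell genes (32 genes, median -0.37). The interferon list lay -0.20 below them (95% bootstrap interval over genes -0.42 to -0.07). The cell cycle list lay -0.13 below (interval -0.31 to 0.04) and the Wnt list -0.13 below (interval -0.49 to 0.14), and both of these intervals reach 0. The bootstrap treats genes as independent, and the reference genes did not follow dilution alone. Squamous markers were lower in Vanillin than in Mock (median -0.78), yet so were 7 of 13 goblet cell markers, with 2 higher (median -0.233). Of 19 colonocyte markers, 7 were higher and 6 lower there. The intervals therefore cannot decide on dilution for any of the 3 lists. An effect of vanillin on these genes stays open for all 3 lists.

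With 3 arrays against 3 there are 10 splits, so a share under 0.05 cannot be reached. In Sham minus Mock 1 of 10 splits, the real one, gave as many probes (15787, highest other 1). In Vanillin minus Sham it was also 1 of 10 (12659, highest other 1), and in Vanillin minus Mock 1 of 10 (13404, highest other 217).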
